A study of Sus scrofa with 3 samples.

How the data were processed

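The data were UMI counts per gene and spot for 3 sections of pig longissimus dorsi, 1 from a Tibetan and 2 from Berkshire pigs. Per the labels' protocols, sections of 15 µm were placed on a Visium capture area, libraries were sequenced to a saturation above 90%, and porcine RNA added as carrier made up about 25% of the libraries. Whether reads of that carrier entered the counts is not given in the sources used here. Per the submitters' processing notes the counts were made with Space Ranger 1.1 against Sscrofa11.1. The deposited values are raw counts of UMIs, not normalized, for the spots kept in the filtered matrix. Positions of spots and tissue images were not used here, so classes of spots rest on counts alone and no spot was checked against histology.

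The 31909 features were named from the feature lists. Of 15209 features given by identifier only, 797 were named from a gene name table, and 14412 stayed without a symbol. MYH1, MB and IGF2 were not analysed here. MYH2 and MYH4 stand at the end of the feature list, apart from their chromosomal neighbours. Gene positions come from the RefSeq annotation of the same assembly, Sscrofa11.1. Features without a symbol held 19.0% of UMIs in the Tibetan section, 20.5% in Berkshire 1 and 21.7% in Berkshire 2, the ribosomal RNA feature RN18S held 3.17, 2.29 and 2.65%, and mitochondrially encoded genes held 16.8, 13.9 and 12.2%.

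Spots with fewer than 100 UMIs were left out, which removed 1 spot in all. No doublet caller was run, since a spot is a region. Because spots of 1 animal are not replicates, counts were summed over spots per section, or per section and class of spots. Slow-rich and fast-rich spots had at least 10 UMIs of MYH7, MYH2 and MYH4 and a MYH7 share at or above the 75th or at or below the 25th percentile of their section. MYH2-rich and MYH4-rich spots were taken by the same percentiles of the MYH2 share of MYH2 and MYH4 UMIs, among spots that were not slow-rich. The 3 myosin features were removed from these sums. The classes are ranges of a share, and the fast-rich limit was 0 in the Tibetan section and Berkshire 2 and 0.0354 in Berkshire 1. The 378 Tibetan and 180 Berkshire 2 fast-rich spots thus had no MYH7 UMI, among as few as 10 myosin UMIs. Counting the fast-rich spots themselves, 412 Tibetan, 977 Berkshire 1 and 200 Berkshire 2 spots had a MYH7 share within 0.05 of this limit. For the breeds inside fibre classes, fixed MYH7 shares of at least 0.5 and at most 0.1 were used.

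Sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with the section as a block in the fibre contrasts, where both classes come from the same animal. The standard error of a log2 difference was taken from the estimate and its F statistic, and does not measure the spread over the animals. DESeq2 1.42.0 was the alternative. The breed fit has 1 Tibetan section, assumed to vary like the Berkshire ones, so breed results are given by a rule of size: a mean of at least 20 CPM and a Tibetan CPM at least 2-fold outside both Berkshire values. CPM, computed here from the deposited counts with TMM scaling, carry exact Poisson intervals for the Tibetan section and the SD of 2 Berkshire sections. A count of 0 was set to 3 counts per section in folds. Intervals are at 95% and cover counting error only.

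The 22 gene lists were slow and fast sarcomere, glycolysis and glycogen, nuclear-encoded respiratory chain, mitochondrially encoded, tricarboxylic acid cycle, fatty acid oxidation, fatty acid and triglyceride synthesis, markers of adipocytes, matrix and fibroblasts, endothelium, smooth muscle and pericytes, leukocytes, satellite cells, Schwann cells and erythrocytes, hypoxia response, immediate early and heat shock, atrophy and proteolysis, growth factor axis, ribosomal proteins and proteasome. They were tested in the fibre contrasts with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one. No list call in either contrast held with an estimated correlation. For the breeds each list's median log2 difference, with 1 CPM added, was ranked among 10000 random lists of the same size, drawn within 100 expression ranks of each member.

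Designs, lists, the rule for named genes and all alternatives except those leaving out RN18S and the 2 most abundant unnamed features were set before the data were examined. The rule took, in the fibre contrasts, the 10 genes in each direction with the largest fold among those with a symbol, a mean of at least 50 CPM, an adjusted p under 0.05 and the same sign in the 3 sections, and 5 with the smallest p where a direction had fewer than 5. For the breeds it took the 10 in each direction with the largest fold against the nearer Berkshire section, and for each list up to 3 past the threshold and 1 not past it. Inside fibre classes the genes named for the whole section are given, a choice made after the data were seen, because the rule there picked genes with few UMIs. Further members of the synthesis, adipocyte and fatty acid oxidation lists (ME1, ACLY, ELOVL5, CIDEC, ACADVL, HADHA, CPT1B and SLC25A20) are named beyond the rule and were chosen after their values were seen.

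The fits were tested on simulated data with 200 changed genes each. At 4-fold they recovered 89.4% for slow-rich against fast-rich spots (3384 genes), 87.9% for MYH2-rich against MYH4-rich spots (2076 genes), 66.7% for the breeds over whole sections (9925 genes), 65.2% and 60.6% in slow-dominant (2071 genes) and fast-dominant spots (6630 genes) and 39.4% for the interaction. At 2-fold the recovery over whole sections was 14.9%. Alternatives were other scalings, no filter on low counts, DESeq2, other limits on spots and classes, thinned spots, leaving out abundant genes, other fold limits, no block, and each section left out in turn. Shares of spots were computed in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.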

Results

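Spatial transcriptomes were measured on cryosections of the longissimus dorsi, the main loin muscle, of 1 Tibetan pig and 2 Berkshire pigs. Each section was laid on a barcoded capture array, on which a spot is a small region of tissue that can hold parts of several fibres and other cells. The Tibetan section gave 3077 spots and 2684046 UMIs (unique molecular identifiers, counts of captured transcripts), with a median of 735 UMIs and 277 genes per spot. The first Berkshire section (Berkshire 1) gave 3601 spots, of which 1 held too few UMIs and was left out, with 3900998 UMIs and a median of 816 UMIs per spot. The second Berkshire section (Berkshire 2) gave 4167 spots, 2309944 UMIs and a median of 410 UMIs per spot. The animal was the replicate throughout. The labels put no replicate behind the Tibetan pig, so a difference between the breeds cannot be separated from a difference between individual animals or sections. The sample titles of the Tibetan section and Berkshire 1 share a suffix that Berkshire 2 lacks, and what it stands for is not stated, so list medians and myosin shares are given against each Berkshire section. The Tibetan sample's title and its count table carry different animal numbers; the assignment given with the series was followed.

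The make-up of myosin heavy chains, the motor proteins that set fibre type, was compared first. MYH2, the heavy chain of fast oxidative fibres, dominated the Tibetan section with 72.9% of the summed MYH7, MYH2 and MYH4 UMIs, against 32.6% ± 15.6 (SD, n = 2) in the Berkshire sections. MYH4, the heavy chain of the fastest glycolytic fibres, held 12.01% in the Tibetan section and 47.3% ± 17.4 (SD, n = 2) in the Berkshire sections. MYH7, the slow heavy chain, held 15.1% in the Tibetan section and 20.1% ± 1.80 (SD, n = 2) in the Berkshire sections. For each of the 3 genes the Tibetan share lay outside both Berkshire shares by more than the exact binomial intervals, which cover counting error only. The Berkshire sections also differed from each other: MYH2 held 21.6% in Berkshire 1 and 43.6% in Berkshire 2, MYH4 held 59.6% and 35.0%, and MYH7 held 18.8% and 21.3%. No test between breeds was run for these shares.

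**Figure D1:**
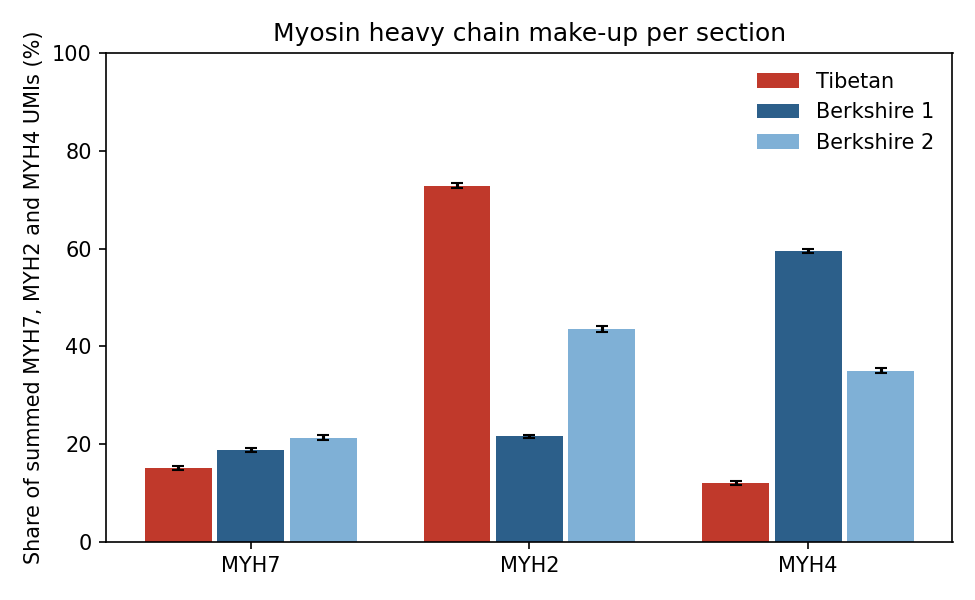
Share of the summed MYH7, MYH2 and MYH4 UMIs (%, y axis) taken by each gene (x axis) in the Tibetan and both Berkshire sections; bars are 1 section each and error bars are exact 95% binomial intervals. MYH2 takes 72.9% in the Tibetan section and MYH4 takes 59.6% in Berkshire 1.

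For MYH2 and MYH4 the contrast appeared spot by spot as well. Among spots with at least 10 myosin UMIs, MYH2 made up a share above 0.5 in 86.3% of 1221 Tibetan spots (exact 95% interval 84.3 to 88.2%), in 8.30% of 2156 Berkshire 1 spots (7.17 to 9.55%) and in 30.3% of 690 Berkshire 2 spots (26.9 to 33.9%). MYH4 did so in 0.491% of the Tibetan spots (0.181 to 1.07%), in 68.6% of Berkshire 1 spots and in 22.5% of Berkshire 2 spots. MYH7 led 7.94% of Tibetan spots, between the 7.75% of Berkshire 1 and the 20% of Berkshire 2 spots. MYH7 (ENSSSCG00000002029) lies on chromosome 7 from 75650841 to 75672908 of Sscrofa11.1. MYH4 (ENSSSCG00000018003, chromosome 12, 55190545 to 55216294) and MYH2 (ENSSSCG00000029441, 55252974 to 55278820) flank MYH1 (55225581 to 55251495), which was not analysed here, so the shares leave this fast isoform out. Reads shared between these near-identical neighbours could have been split or assigned unevenly, so the balance of MYH2 and MYH4 is uncertain.

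Spots with a high MYH7 share (slow-rich) were then compared with spots of a low one (fast-rich) inside each animal. Slow-rich spots held 45.0% MYH7 and 49.6% MYH2 in the Tibetan section, 47.1% and 20.7% in Berkshire 1, and 69.3% and 19.8% in Berkshire 2. Fast-rich spots held 84.5% MYH2 and 15.5% MYH4 in the Tibetan section, 22.4% and 77.3% in Berkshire 1, and 51.3% and 48.7% in Berkshire 2. The contrast thus set different fibre mixtures against each other in the 3 sections. Genes of the slow contractile apparatus were far higher in slow-rich spots: the slow troponins TNNI1, TNNT1 and TNNC1 were higher by log2 3.10 ± 0.13, 3.06 ± 0.12 and 2.91 ± 0.11 (standard error of the fit to 3 animals). The light chains MYL3 (3.23 ± 0.19) and MYL2 (3.05 ± 0.12), tropomyosin TPM3 (3.04 ± 0.14), the Z-disc protein MYOZ2 (3.10 ± 0.19), the slow calcium pump ATP2A2 (2.99 ± 0.14) and the muscle LIM protein CSRP3 (2.93 ± 0.31) rose by similar amounts, and LMCD1 rose by 1.88 ± 0.22. The errors come from a fit that shares variance over genes and do not measure the spread over animals. In the Tibetan section, Berkshire 1 and Berkshire 2, LMCD1 was at 1.00, 2.15 and 3.97, and MYL3 at 3.13, 2.84 and 5.41. Each of these genes was higher in slow-rich spots of all 3 animals, which the rule for named genes required. Their adjusted p ran from 5.46e-23 for TNNC1 to 2.64e-08 for LMCD1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The myosin genes that define the classes were removed before the fit.

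Collagens and other matrix genes stood among the genes lower in slow-rich spots. The Wnt modulator SFRP4 was lower by log2 -1.31 ± 0.32, collagen COL14A1 by -1.26 ± 0.20, fatty acid synthase FASN by -1.23 ± 0.22, COL1A2 by -0.998 ± 0.115 and COL1A1 by -0.97 ± 0.11. FASN rested mainly on the Tibetan section, with 125 UMIs in slow-rich and 298 in fast-rich spots. Berkshire 1 held 16 and 17 FASN UMIs and Berkshire 2 held 0 and 2. MFAP5 (-0.98 ± 0.22), fibronectin FN1 (-0.95 ± 0.17), ECM2 (-0.93 ± 0.26), ANXA1 (-0.85 ± 0.23) and UBE2D4 (-0.84 ± 0.24) completed the named genes, with adjusted p from 1.32e-08 for COL1A2 to 0.0189 for UBE2D4. In all, 250 of 3384 genes passed an adjusted p of 0.05, with 179 higher and 71 lower in slow-rich spots.

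**Figure D2:**
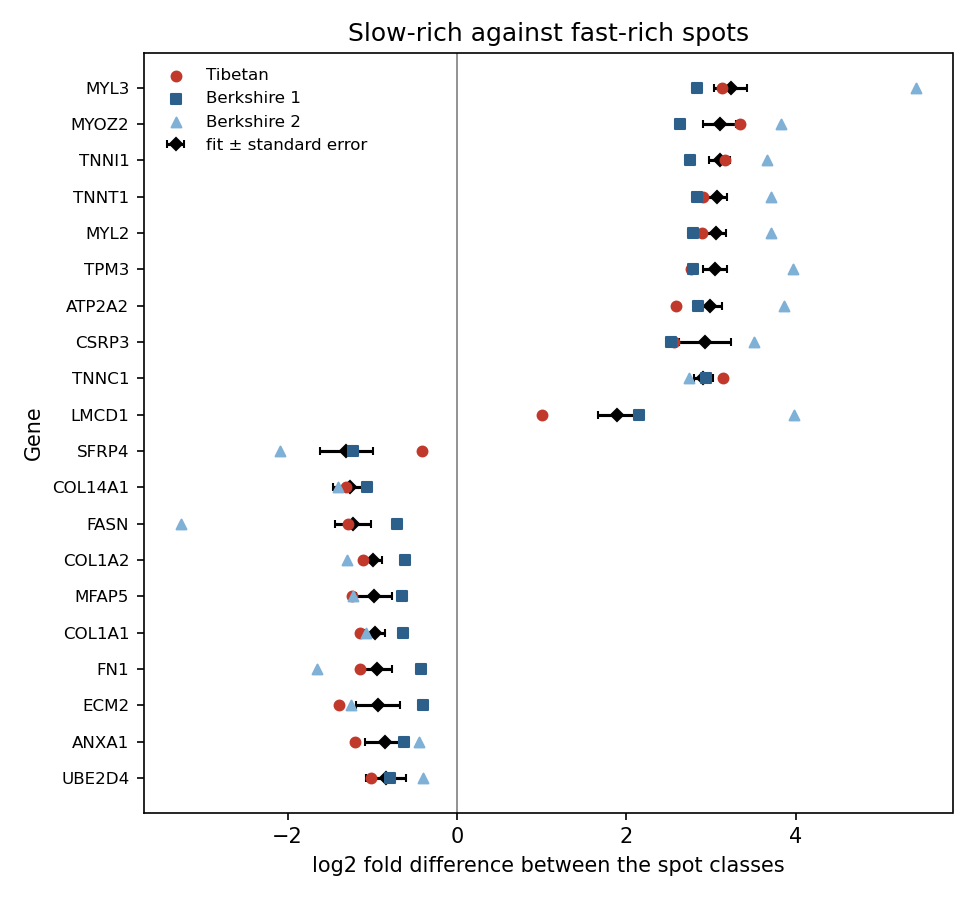
Log2 fold difference of slow-rich against fast-rich spots (x axis) for the named genes (y axis); coloured points are the 3 sections and black diamonds are the fitted value with its standard error. TNNC1, at 2.91, and the other slow contractile genes lie right of 0 in every section, and the collagens lie left of 0. Named genes were chosen to share their sign over the sections.

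By gene list, all 11 tested slow sarcomere genes rose and 9 of 13 fast sarcomere genes fell, among them MYLPF (-0.50 ± 0.11), MYL1 (-0.47 ± 0.10), TNNC2 (-0.50 ± 0.10) and TNNI2 (-0.56 ± 0.10), while MYOZ1 stood at -0.01 ± 0.10. Adjusted over the list alone, the counts were again 11 and 9. The camera test with a preset correlation called both lists, but with an estimated correlation the adjusted p was 0.0709 for the slow and 0.249 for the fast list.

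Many, though not all, genes of mitochondrial energy metabolism were called higher in slow-rich spots, and 0 were called lower. Of 61 nuclear-encoded respiratory chain genes 37 rose (53 adjusted over the list alone), including COX6A2 (0.97 ± 0.11), COX7A1 (1.02 ± 0.11) and COX7C (0.54 ± 0.11), while NDUFB4 stood at 0.22 ± 0.13. Of 13 mitochondrially encoded genes 11 rose (12 adjusted over the list alone), including COX2 (1.04 ± 0.10) and COX3 (1.01 ± 0.10). Of 18 tricarboxylic acid cycle genes 8 rose (12 adjusted over the list alone), with IDH2 at 0.90 ± 0.13 and MDH2 at 0.85 ± 0.15. Of 18 fatty acid oxidation genes 7 rose (11 adjusted over the list alone), including the fatty acid carrier FABP3 (1.47 ± 0.19), the transporter CD36 (0.70 ± 0.16) and ACSL1 (0.56 ± 0.15), while the lipase LPL stood at 0.55 ± 0.18 and did not pass. Camera called these 4 lists with a preset correlation. With an estimated correlation the adjusted p was 0.122 for the respiratory chain, 0.130 for the mitochondrially encoded and tricarboxylic acid cycle lists, and 0.215 for fatty acid oxidation.

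Of 22 glycolytic genes 8 were called lower in slow-rich spots (13 adjusted over the list alone), and 14 did not pass. GAPDH was lower by -0.35 ± 0.10, ENO3 by -0.35 ± 0.10 and ALDOA by -0.49 ± 0.10, while PYGM stood at -0.23 ± 0.10 and PRKAG3, a regulator of muscle glycogen, at -0.66 ± 0.23 (adjusted p = 0.0719). Of 16 matrix and fibroblast markers 9 were lower (12 adjusted over the list alone), including COL3A1 (-0.71 ± 0.11) and DCN (-0.51 ± 0.11), while COL6A3 stood at -0.29 ± 0.15. Of 5 adipocyte markers ADIPOQ (-0.73 ± 0.21) and PLIN1 (-1.50 ± 0.37) were lower (3 adjusted over the list alone) and FABP4 stood at -0.44 ± 0.18. Camera called the 3 lists with a preset correlation, and with an estimated one the adjusted p was 0.263 for glycolysis, 0.130 for matrix markers and 0.459 for adipocyte markers.

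Among the remaining lists, 1 of 9 endothelial markers rose (RAMP2, 0.75 ± 0.23), 1 of 4 synthesis genes fell (FASN), 1 of 3 growth factor genes fell (IGFBP5, -0.80 ± 0.21), 1 of 5 hypoxia genes rose (EPAS1, 0.73 ± 0.22) and 2 of 8 immediate early and heat shock genes rose (CRYAB, 0.81 ± 0.11, and HSPB6, 1.46 ± 0.16). Adjusted over the list alone, 2 endothelial genes were higher, 2 synthesis and 3 growth factor genes were lower, 1 hypoxia gene was higher and 1 lower, 2 immediate early and heat shock genes were higher, and 1 smooth muscle gene was higher and 2 were lower. Of 59 ribosomal protein genes 1 passed (RPLP2, 0.40 ± 0.10), and 0 passed among 29 proteasome, 9 atrophy, 7 smooth muscle and 7 leukocyte genes by edgeR, in a fit where 570 genes of all 3384 had an unadjusted p under 0.05. With a preset correlation camera called the endothelial, synthesis, growth factor and ribosomal lists as well, and with an estimated one the adjusted p was 0.454, 0.357, 0.250 and 0.250. Fewer than 3 satellite cell, Schwann cell and erythrocyte markers were tested, with NCAM1 at -0.72 ± 0.42, PMP22 at -0.15 ± 0.30 and HBB at 0.04 ± 0.11. MSTN (-1.11 ± 0.41), CAST (-0.40 ± 0.21) and CAPN1 (-0.36 ± 0.34) did not pass the test.

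DESeq2 called 115 genes, the fit without an animal block 23, spots thinned to equal depth 103, and the fits without the Tibetan section, Berkshire 1 or Berkshire 2 called 140, 149 and 155. Scaling by total counts moved the median of all genes by -0.21 on the log2 scale and turned the split from 179 higher and 71 lower to 93 higher and 196 lower. Slow-rich spots were also deeper than fast-rich ones, with median UMIs of 1269 against 879 in the Tibetan section, 1529 against 924 in Berkshire 1 and 1126 against 805.5 in Berkshire 2.

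Within the fast spots, those richest in MYH2 were compared with those richest in MYH4. The MYH2-rich spots carried more of the beta globin HBB (log2 1.58 ± 0.18, adjusted p = 1.96e-05), the Wnt antagonist FRZB (1.75 ± 0.32) and the lipid-handling genes ACSL1 (1.03 ± 0.19) and FABP3 (1.01 ± 0.23). Also higher were the myosin-binding protein MYBPC1 (0.94 ± 0.13), the LIM protein FHL1 (0.92 ± 0.12), the pyruvate dehydrogenase kinase PDK4 (0.87 ± 0.17), ABRA (0.88 ± 0.22), the small heat shock protein HSPB7 (0.87 ± 0.21) and GSPT1 (1.16 ± 0.30). The glycolytic enzyme ALDOA was the 1 gene called lower, at -0.36 ± 0.09 (adjusted p = 0.0380). All 11 differed in the same direction in the 3 animals, which the rule for named genes required. Some differed less in the Tibetan section. HSPB7 was at 0.11 there (31 and 26 UMIs), against 1.21 in Berkshire 1 and 0.88 in Berkshire 2. ACSL1 and FABP3 were at 0.26 there (20 and 15 UMIs each), against 1.03 and 1.39 for ACSL1 and 1.19 and 1.18 for FABP3. In all, 37 of 2076 genes passed, 36 of them higher. The classes were relative to each section: Tibetan MYH4-rich spots held 64.6% MYH2 and 30.1% MYH4, while Berkshire 1 MYH2-rich spots held 50.3% MYH2 and 41.1% MYH4.

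**Figure D3:**
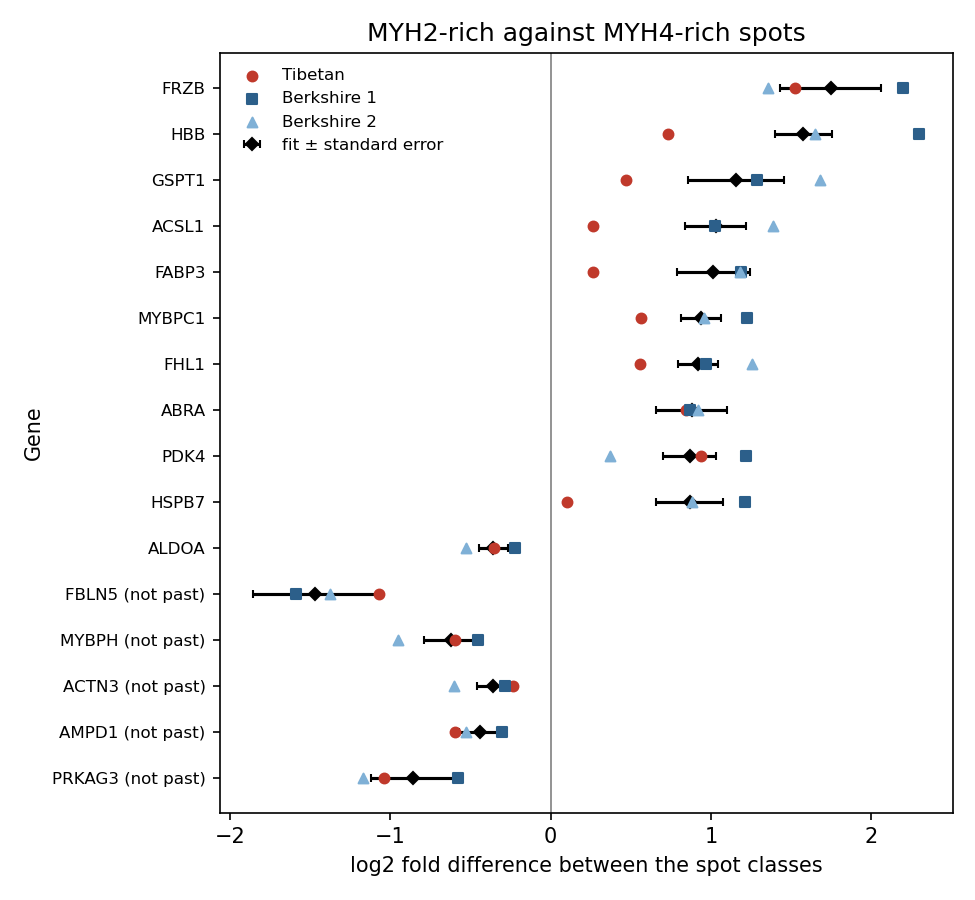
Log2 fold difference of MYH2-rich against MYH4-rich fast spots (x axis) for the named genes (y axis); coloured points are the 3 sections, black diamonds are the fitted value with its standard error, and genes marked as not past did not pass an adjusted p of 0.05. HBB, at 1.58, lies right of 0 in every section. Named genes were chosen to share their sign over the sections.

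The slow myosin moved with this contrast: MYH7 held 6.35% in MYH2-rich and 5.38% in MYH4-rich spots of the Tibetan section, 8.56% and 6.49% in Berkshire 1, and 12.03% and 9.09% in Berkshire 2. Mitochondrially encoded genes made up 10 of the 36 higher calls, out of 13 tested (11 adjusted over the list alone), with COX2 at 0.51 ± 0.08, COX3 at 0.48 ± 0.08 and ND4L at 0.43 ± 0.11, the last not past the threshold. Of 61 nuclear-encoded respiratory chain genes 4 rose (16 adjusted over the list alone), among them COX5A (0.70 ± 0.14) and NDUFA4 (0.54 ± 0.13). With an estimated correlation the adjusted p of both lists was 0.316. ANKRD1 was the 1 of 9 slow sarcomere genes that passed (0.86 ± 0.21; 7 adjusted over the list alone), ACSL1 and FABP3 were the 2 of 13 fatty acid oxidation genes (3 adjusted over the list alone), CRYAB (0.73 ± 0.12) was the 1 of 6 immediate early and heat shock genes (2 adjusted over the list alone), and ALDOA the 1 of 21 glycolytic genes (3 adjusted over the list alone). Camera called these lists with a preset correlation, and with an estimated one the adjusted p was 0.380 for glycolysis and 0.316 for the other 3.

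Genes lower in MYH2-rich spots with the smallest p that missed the threshold were FBLN5 (-1.47 ± 0.38), MYBPH (-0.62 ± 0.17), the fast alpha-actinin ACTN3 (-0.36 ± 0.10), AMPD1 (-0.44 ± 0.13) and PRKAG3 (-0.86 ± 0.26), with adjusted p from 0.0504 to 0.117. By edgeR 0 genes passed among 15 matrix, 4 adipocyte, 13 fast sarcomere and 18 tricarboxylic acid cycle genes, where 6, 2, 2 and 2 passed adjusted over the list alone, and camera's adjusted p with an estimated correlation was 0.401, 0.380, 0.371 and 0.413. The test also gave 0 among 58 ribosomal, 28 proteasome, 7 atrophy, 6 smooth muscle, 6 leukocyte, 5 hypoxia and 4 endothelial genes (1 smooth muscle, 1 leukocyte and 1 endothelial gene adjusted over the list alone), in a fit where 239 genes had an unadjusted p under 0.05. With a preset correlation camera called the ribosomal list lower and the smooth muscle list higher, and with an estimated one the adjusted p was 0.316 and 0.401. DESeq2 called 22 genes in all. This contrast was fragile: 0 genes passed with a split at the median or without the animal block, and 13, 20 and 10 passed without the Tibetan section, Berkshire 1 and Berkshire 2. Relative log expression scaling called 45 higher and 17 lower genes, and scaling by total counts 32 higher and 35 lower.

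Whether the fibre contrast differed between the breeds was tested by an interaction term. By edgeR 0 of 3384 genes passed, 156 had an unadjusted p under 0.05, and DESeq2 also called 0. LMCD1 had the smallest p, with an interaction of -1.58 (adjusted p = 0.212), and its slow-rich against fast-rich difference was 1.00 in the Tibetan section, 2.15 in Berkshire 1 and 3.97 in Berkshire 2. The classes themselves differed between sections, with a MYH7 share in slow-rich spots of 45.0% in the Tibetan section, 47.1% in Berkshire 1 and 69.3% in Berkshire 2. Fast-rich spots differed as well, with mostly MYH2 in the Tibetan section and mostly MYH4 in Berkshire 1. In simulated data the interaction recovered 39.4% of 4-fold and 8.96% of 2-fold changes.

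Between the breeds, over whole sections, genes of fatty acid synthesis were among those furthest apart. The desaturase SCD (ENSSSCG00000010554, chromosome 14, 111461560 to 111478033) measured 1295 in the Tibetan section (CPM, counts scaled to a common library total; exact Poisson interval 1251 to 1340) and 7.92 ± 7.07 CPM (SD, n = 2) in the Berkshire sections. FASN (ENSSSCG00000029944, chromosome 12, 922405 to 937560) measured 1039 CPM (999.7 to 1079) against 25.5 ± 17.2. The lipogenic regulator THRSP measured 275 against 5.59 ± 1.41 CPM, the elongase ELOVL6 157 against 8.95 ± 3.81 and the triglyceride synthesis enzyme DGAT2 138 against 10.7 ± 8.57. Of 13 synthesis genes 8 lay at least 2-fold above both Berkshire sections, the others being ME1 (149 CPM, 4.79-fold above the nearer Berkshire section), ACLY (84.9 CPM, 7.45-fold) and ELOVL5 (64.2 CPM, 5.28-fold), while AGPAT2 stood at 39.1 against 35.7 ± 0.770 CPM.

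**Figure D4:**
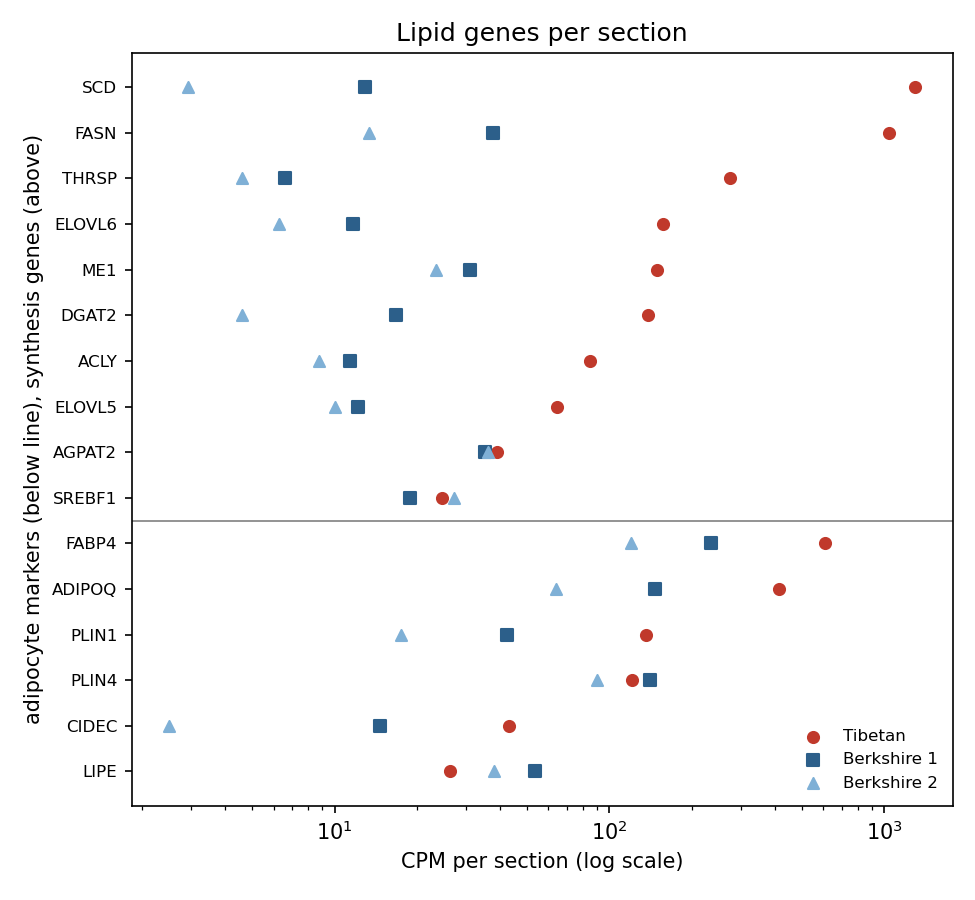
CPM per section (x axis, log scale) for 10 synthesis genes and 6 adipocyte markers with a mean of at least 20 CPM (y axis); each point is 1 section. SCD is at 1295 CPM in the Tibetan section and at 12.9 and 2.92 CPM in the Berkshire sections.

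Other genes far higher in the Tibetan section were the stress-induced transcription factor ATF3 (257 CPM against 8.89 ± 2.18; SD, n = 2), the glycolytic regulator PFKFB3 (211 against 10.1 ± 0.0839), the Wnt modulator SFRP2 (60.3 against 4.95 ± 0.516) and a feature named DEFB1 (54.0 against 5.25 ± 1.53), a name that 2 features carry. A signal recognition particle RNA feature, Metazoa_SRP, measured 150 CPM with 2 UMIs in Berkshire 1 and 0 in Berkshire 2; it belongs to a repeated RNA family, so its reads are uncertain. Lower in the Tibetan section were complement C3 (4.70 CPM against 48.8 ± 14.2), ZFAND2A (5.09 against 35.0 ± 14.8), FNTB (14.1 against 68.9 ± 4.25), CTXN3 (14.1 against 71.0 ± 16.0), the muscle ubiquitin ligase FBXO32 (89.6 against 372 ± 40.9), BHLHE41 (13.7 against 54.9 ± 5.74), ABCA5 (9.39 against 34.4 ± 0.307), TMEM140 (24.7 against 99.2 ± 17.0), ACSL1 (82.6 against 319 ± 42.9) and SLC12A2 (72.4 against 267 ± 21.04).

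Of 9925 genes 75.9% lay outside both Berkshire values, where chance gives 66.7%. In all, 199 of 3846 genes lay at least 2-fold outside both Berkshire sections, 91 above and 108 below, against 33 when Berkshire 1 was taken as the section apart and 19 for Berkshire 2, and the count was 321 without Berkshire 1 and 339 without Berkshire 2. Scaling by total counts moved the median of all genes by -0.14 on the log2 scale and gave 67 above and 154 below. The edgeR test, with 1 Tibetan section assumed to vary like the Berkshire ones, called 356 of 9925 genes (222 higher, 134 lower), but the count ran from 56 without mitochondrially encoded and haemoglobin genes to 936 with total counts (354 higher, 582 lower), and DESeq2 called 105. For that reason genes are described by size.

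Markers of fat, connective tissue and vessel walls were also higher in the Tibetan section. Of 9 adipocyte markers 4 lay above the 2-fold limit: FABP4 (609 CPM against 177 ± 80.5; SD, n = 2; 234 in Berkshire 1 and 120.1 in Berkshire 2), ADIPOQ (414 against 105 ± 58.7; 147 and 63.8), PLIN1 (136 against 30.03 ± 17.7) and CIDEC (43.1 against 8.60 ± 8.62), while PLIN4 stood at 121 against 115 ± 35.5. Of 18 matrix markers 5 did, including COL3A1 (3598 against 1252 ± 468), COL1A2 (2594 against 944 ± 216) and COL1A1 (1852 against 681 ± 105), while SPARC was 1.81-fold above the nearer Berkshire section. Of 8 smooth muscle and pericyte markers 5 did, including TAGLN (385 against 166 ± 24.7) and ACTA2 (364 against 154 ± 16.1). The medians of these 3 lists and of the synthesis list lay at the 100th percentile of 10000 expression-matched random lists against either Berkshire section. Against Berkshire 1 the median log2 difference was 2.79 for synthesis, 1.38 for adipocyte, 0.65 for matrix and 1.34 for smooth muscle genes, and against Berkshire 2 it was 3.14, 2.33, 1.02 and 1.098. Berkshire 2 ranked against Berkshire 1 gave percentile 0 for synthesis and adipocyte genes, 0.06 for matrix and 89.3 for smooth muscle genes. The medians there were -0.54, -0.96, -0.25 and 0.10, so extreme ranks also arose between 2 animals of 1 breed.

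Of 19 fatty acid oxidation genes 13 lay below both Berkshire sections, and 6 of them by at least 2-fold: ACSL1, FABP3 (85.3 CPM against 229 ± 27.996), ACADVL (57.1 against 136 ± 0.648), HADHA (50.5 against 114 ± 11.3), CPT1B (19.6 against 61.9 ± 13.2) and SLC25A20 (11.7 against 30.6 ± 3.22). LPL, which releases fatty acids from circulating lipid, lay above at 346 against 113 ± 30.8. CD36 stood at 190 against 236 ± 11.6. The list's median was -0.56 against Berkshire 1 (percentile 0.0900) and -0.73 against Berkshire 2 (percentile 0). Berkshire 2 against Berkshire 1 gave -0.20 (percentile 0.73). Proteasome genes were lower too, with 33 of 35 below both Berkshire sections and 2 past the 2-fold limit, PSMA4 (51.7 against 133 ± 2.45) and PSMD12 (47.4 against 117 ± 13.2), and medians of -0.58 and -0.48.

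Mitochondrially encoded genes were modestly higher in the Tibetan section, 12 of 13 above both Berkshire sections and 0 past the 2-fold limit, with medians of 0.41 and 0.47 (percentiles 99.8 and 99.9). Berkshire 2 against Berkshire 1 gave -0.097 (percentile 5.155). Nuclear-encoded respiratory chain genes had medians of -0.25 and -0.11, with 40 of 61 below both Berkshire sections. Slow sarcomere genes had medians of -0.31 and -0.43, with ANKRD1 above the 2-fold limit (764 CPM against 302 ± 60.8). Endothelial markers had medians of 0.78 and 0.65 with 0 of 12 past the limit. For the remaining lists 2 or fewer genes passed: UGP2 (98.2 against 301 ± 32.9) and GBE1 (50.5 against 22.4 ± 2.60) among 22 glycolytic genes, IGFBP5 (167 against 68.0 ± 2.34) among 7 growth factor genes, CDH15 (8.61 against 29.7 ± 6.66) among 5 satellite cell genes, FBXO32 among 10 atrophy genes and ATF3 among 13 immediate early and heat shock genes. By the same rule 0 passed among 14 fast sarcomere, 18 tricarboxylic acid cycle, 12 leukocyte, 4 Schwann cell, 3 erythrocyte, 13 hypoxia and 60 ribosomal genes.

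Of the other genes named in advance, MYH4 measured 1335 CPM in the Tibetan section against 6007 ± 2919 (SD, n = 2; 8071 in Berkshire 1 and 3943 in Berkshire 2), MYH2 8103 against 3918 ± 1404 and MYH7 1677 against 2475 ± 101. EPAS1, a hypoxia-responsive transcription factor, measured 130 against 70.2 ± 2.48 CPM and PRKAG3 56.8 against 124 ± 55.0, with 85.3 in Berkshire 1 and 163 in Berkshire 2. The proteolysis genes CAST (87.3 against 96.4 ± 1.22) and CAPN1 (33.3 against 35.1 ± 2.79), the growth inhibitor MSTN (27.0 against 36.1 ± 6.23) and VEGFA (5.87 against 4.83 ± 0.337) were measured as well. MYH4 passed the 2-fold limit; MYH2, MYH7, EPAS1, PRKAG3, CAST, CAPN1 and MSTN did not, and VEGFA was too low to be eligible.

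The share of spots with at least 1 UMI of a marker list was compared after each spot was thinned to 312 UMIs. Spots with fewer UMIs were dropped, which left out 29 Tibetan, 109 Berkshire 1 and 1032 Berkshire 2 spots. The thinned shares of Berkshire 2 thus cover its deeper spots only. Adipocyte markers appeared in 19.9% of Tibetan spots and in 8.58% ± 2.08 (SD, n = 2) of Berkshire spots, and synthesis genes in 34.1% against 4.70% ± 0.689. Before thinning these were 32.9% against 18.0% ± 10.6 and 51.0% against 10.6% ± 5.39. After thinning matrix markers appeared in 80.6% against 64.0% ± 6.96, smooth muscle markers in 19.5% against 10.4% ± 0.214, endothelial markers in 13.7% against 8.18% ± 1.11 and erythrocyte markers in 19.9% against 14.0% ± 5.20. Thinning lowered the Tibetan minus Berkshire difference from 12.2 to 5.54 percentage points for endothelial, from 10.6 to 5.99 for erythrocyte, from 16.6 to 9.10 for smooth muscle and from 8.18 to 1.00 for leukocyte markers. Leukocyte markers (30.4% against 29.4% ± 2.12) and Schwann cell markers (2.13% against 2.14% ± 0.00793) were as close as 1.00 and -0.0102 percentage points to the Berkshire mean. A like share of spots does not exclude a difference in level. The 4 Schwann cell genes had a median log2 difference of 1.76 against Berkshire 1 and 0.74 against Berkshire 2. Berkshire 2 against Berkshire 1 gave 0.61. Satellite cell markers appeared in 1.28% against 2.32% ± 0.0369, and before thinning in 3.09% against 5.41% ± 2.49.

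The breed comparison was repeated inside fibre classes. In fast-dominant spots, where MYH7 held a share of at most 0.1, the genes named for the whole section are given as values only, since these spots are part of the sums from which the genes were chosen. SCD measured 911 CPM against 5.83 ± 8.24 (SD, n = 2), FASN 757 against 30.3 ± 11.8 and ATF3 332 against 8.15 ± 2.26, while ACSL1 measured 78.6 against 299 ± 25.2. In slow-dominant spots, where MYH7 held a share of at least 0.5, 10 of these genes were tested, among them FASN, which was at least 10.06-fold higher than the floor of 3 counts per Berkshire section, and ATF3 (255 CPM against 4.61 ± 6.52). The slow-dominant spots are part of the same whole-section sums, so their values are no independent repeat either. FABP3 was lower there as well (110 against 576 ± 78.7).

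In slow-dominant spots 471 genes lay 2-fold outside both Berkshire sections, against 187 and 280 with Berkshire 1 or Berkshire 2 as the section apart (1064 without Berkshire 1, 751 without Berkshire 2), and edgeR called 73 genes where DESeq2 called 0 (50 at an unadjusted p under 0.05). In fast-dominant spots the counts were 256 against 77 and 150 (662 and 440 without Berkshire 1 and Berkshire 2), and edgeR called 184 genes (106 higher, 78 lower) where DESeq2 called 19. Scaling by total counts moved the median of all genes by -0.14 and -0.33 on the log2 scale, and changed the edgeR split to 17 higher and 49 lower of 66 in slow-dominant and to 42 higher and 155 lower in fast-dominant spots. The slow-dominant sums held 175238 UMIs in the Tibetan section, 420141 in Berkshire 1 and 198239 in Berkshire 2, so most single genes rested on few UMIs. Of the 471 genes past the 2-fold limit there, 115 lay above and 356 below. Without Berkshire 1 the split was 552 above and 512 below, and without Berkshire 2 it was 252 above and 499 below.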

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

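The tests of synthesis UMIs per adipocyte UMI, of the genes of the MYH2-rich contrast and of the immediate early list were chosen only after the result was seen, and the 8 fasting genes were picked after FBXO32 and ACSL1 had been seen to be lower, though before their own values were.

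For 10 list medians the sign in the Tibetan section was opposite to that in both Berkshire sections, in some of them with values near 0. They were picked for this from the lists of both contrasts, and these differences were not tested at the level of lists. For slow-rich against fast-rich spots no single gene passed the interaction test by edgeR (156 had an unadjusted p under 0.05, and DESeq2 called 0), and for MYH2-rich against MYH4-rich spots no interaction was tested. In slow-rich against fast-rich spots the median log2 difference of 5 adipocyte markers was -0.97 in the Tibetan section, 0.00075 in Berkshire 1 and 0.02 in Berkshire 2. In each section this median was the value of FABP4, which had only 14 and 13 UMIs in the Berkshire 2 classes. Leukocyte markers were at -0.26 against 0.24 and 0.34, immediate early and heat shock genes at 0.36 against -0.05 and -0.02, and atrophy genes at 0.074 against -0.22 and -0.28. In MYH2-rich against MYH4-rich spots adipocyte markers (4 genes) were at 0.31 in the Tibetan section against -1.03 and -1.90. Matrix markers (15 genes) were at 0.15 against -0.34 and -0.93, and leukocyte markers (6 genes) at 0.19 against -0.27 and -0.34. Tricarboxylic acid cycle genes were at -0.012 against 0.42 and 0.32, endothelial markers at -0.0057 against 0.33 and 0.67, and proteasome genes at -0.15 against 0.19 and 0.20.

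The synthesis genes were far higher in the Tibetan section. A larger adipocyte content as the whole cause is argued against by the synthesis UMIs per adipocyte marker UMI, which were 2.40 in the Tibetan section, 0.338 in Berkshire 1 and 0.443 in Berkshire 2, 5.42-fold above the nearer Berkshire section. A few very rich spots as the whole cause are argued against as well, although such spots held much of the signal. Without the 5% of spots richest in these UMIs the Tibetan level fell from 3155 to 1434 CPM. That was still above the 221 and 158 CPM of the uncut Berkshire 1 and Berkshire 2 sections. With the same cut in each section it was 14.6-fold above the nearer Berkshire section. This fold says little, since the cut also lowered Berkshire 1 to 98.5 and Berkshire 2 to 36.2 CPM. A different feeding state at sampling may contribute, since 6 of 8 genes known to rise in fasted muscle were below both Berkshire sections, with a median log2 difference of -0.76, among them PDK4 (183 CPM against 423 and 567) and UCP3 (23.5 against 60.8 and 70.5). The labels give no feeding state, and breed, animal and section stay open as untested explanations.

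The second pattern is the larger MYH2 share of the Tibetan section, which could by itself shift genes higher in MYH2-rich spots, though the MYH7 share was somewhat higher in those spots too and the genes need not be specific to MYH2. All 10 mitochondrially encoded genes called in the spot contrast lay above both Berkshire sections, with a median log2 difference of 0.50, which such a share could give. Inside slow-dominant spots, however, 10 of all 13 mitochondrially encoded genes were also above both Berkshire sections and 1 was below both. COX2 (67110 CPM against 57244 and 41769) and ND5 (4477 against 3378 and 2485) were above both there, while COX1 (29893 against 40299.5 and 25059) was not. As MYH2 was higher in slow-dominant spots as well (3862 against 2074 and 2203), other causes stay open. For the 26 other genes called higher in MYH2-rich spots the median was -0.18, with 8 above and 15 below both Berkshire sections. The larger share alone would make them higher as a set, which they were not, though single members went both ways. Nuclear-encoded respiratory chain genes, with a median of 0.35 in the spot contrast, were not higher either. Their medians were -0.25 against Berkshire 1 and -0.11 against Berkshire 2, with 6 above and 40 below both. The larger share alone thus does not account for the values of these genes. ACSL1 and FABP3, higher in MYH2-rich spots, were more than 2-fold lower in the Tibetan section. Uneven assignment of reads among MYH2, MYH4 and the unanalysed MYH1 stays open, as does breed.

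The third pattern is the rise of ATF3, PFKFB3, ANKRD1, XIRP1 and CREM, with fitted log2 differences of 3.08 for XIRP1 and 2.05 for CREM, both chosen after their values were seen. A general immediate early and heat shock response at sampling could raise ATF3 and ANKRD1, but the 12 other members of that list had a median log2 difference of -0.010, with 3 above and 4 below both Berkshire sections. A general rise of these members was thus not seen, though single members went both ways. For the genes of this pattern, handling of the tissue and breed cannot be told apart here.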

How the results depend on the processing

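Alternatives that leave out RN18S and the 2 most abundant unnamed features, in addition to mitochondrially encoded and haemoglobin genes, were chosen after seeing the data, as were the tests by splits and by random classes; the others were set before. Leaving the spot filter out changed no count, and none of the named genes reversed under any alternative. Over the named genes and alternatives, 298 values in slow-rich against fast-rich spots kept their side of the threshold and 44 lost it, in MYH2-rich against MYH4-rich spots 175 kept it, 68 lost it and 13 gained it, and in the breed comparison all 222 kept their direction and side of the limit. The named breed genes were chosen for the largest folds, the smallest being 3.48-fold for SLC12A2. Their staying past a 2-fold limit therefore says little about the other genes. The cause of the changes below was not tested, unless fewer genes or spots are named.

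For slow-rich against fast-rich spots (250 genes) DESeq2 gave 115, spots thinned to equal depth 103 with 1591 genes left to test, the fit without the replicate block 23, and leaving out 1 section 140 to 155. For MYH2-rich against MYH4-rich spots (37 genes) relative log expression scaling gave 62, total counts 67, DESeq2 22, at least 30 myosin UMIs 3 (5 and 4 Tibetan spots left), at least 5 myosin UMIs 14, the extreme 10% of spots 6, a median split 0, the fit without the replicate block 0, and leaving out 1 section 10 to 20. The interaction gave 1 gene with the extreme 10% of spots and 0 under the other alternatives. It and the breed tests by edgeR could not be rerun without a section, since no residual degree of freedom would remain.

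For the breeds over whole sections edgeR called 356 genes, 781 with relative log expression scaling, 936 with total counts, 749 without the filter on low counts, 105 with DESeq2, 56 without mitochondrially encoded and haemoglobin genes, and 56 when RN18S and the unnamed features were left out in addition to these. The 2-fold count of 199 became 635 at 1.5-fold, 48 at 3-fold, 45 at a mean of at least 100 CPM, and 321 to 339 without 1 Berkshire section. In slow-dominant spots the edgeR count of 73 became 31 without the filter on low counts, 0 with DESeq2 and 9 with at least 30 myosin UMIs, and the 2-fold count of 471 became 826 without all of these together (638 without mitochondrially encoded and haemoglobin genes alone), 1022 at 1.5-fold, 171 at 3-fold, 46 at 100 CPM and 751 to 1064 without 1 Berkshire section. In fast-dominant spots the edgeR count of 184 became 109, 19 and 6 under the same 3 settings, and the 2-fold count of 256 became 782 at 1.5-fold, 56 at 3-fold, 38 at 100 CPM, 2015 with at least 30 myosin UMIs (6 Tibetan spots left) and 440 to 662 without 1 Berkshire section. The MYH7 share of the Tibetan section minus the Berkshire mean went from -4.99 to -7.67 percentage points in spots with at least 500 UMIs.

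The slow-dominant comparison rests on 109 Tibetan spots. In 10 splits of the 6 class libraries with the animal as block, 1 split, the real one, gave as many genes in slow-rich against fast-rich spots (250, highest other 0), and likewise 1 in MYH2-rich against MYH4-rich spots (37, highest other 5); 10 splits are too few for a share under 0.05. Random assignment of the same spots, 20 times, gave at most 6 genes against 250 and at most 4 against 37. The first argues against classes drawn at random, and the second, by the limit used, leaves them open for the MYH2 contrast. Such draws even out depth and position between the classes, so they cannot speak to classes that differ in these. The median log2 difference of matrix genes in slow-rich spots was -0.58 after thinning (12 genes) and -0.57 before (16 genes). The classes were chosen before thinning, and drawing UMIs at random keeps the gene proportions of a spot on average. This comparison therefore cannot decide whether the higher depth of slow-rich spots goes with their lower matrix genes.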

Other observations

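Grouping spots by adipocyte marker UMIs was chosen only after the results were seen. Synthesis genes were not spread evenly over the Tibetan section. In the 318 Tibetan spots with 3 or more adipocyte marker UMIs they reached 13309 CPM and held 68.9% of the synthesis UMIs on 16.3% of all UMIs. In the 2064 Tibetan spots without an adipocyte marker UMI they still measured 864 CPM (exact Poisson interval 819.9 to 910.5), above the 834 and 350 CPM in the Berkshire 1 and Berkshire 2 spots with 3 or more adipocyte marker UMIs in value, although the interval of Berkshire 1 reached 928. Berkshire spots without an adipocyte marker UMI measured 148 and 140 CPM. Spots without such a UMI were shallower than the richest spots, with median UMIs of 700.5 and 1032.5 in the Tibetan section, and a spot without a marker UMI can still hold part of an adipocyte.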
